A study of Homo sapiens with 87 samples.

How the data were processed

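The libraries came from HAP1, a near-haploid human line derived from a chronic myeloid leukaemia, and from HAP1 clones in which a gene of the BAF complex had been knocked out. BAF (SWI/SNF) is a chromatin-remodelling complex that moves nucleosomes with the ATPase SMARCA4 or SMARCA2. Per the labels, poly-A RNA was made into stranded libraries and read in a single direction, 50 bases at a time. The 87 samples fall into 2 tables that were handled separately. The knockout table holds 75 libraries in 25 groups of 3, namely wild type and 24 knockout clones of 22 genes, with 2 clones each for ARID1A (618-10 and 618-3) and SMARCA4 (2878-4 and 2878-6). The double-loss table holds 12 libraries in 6 groups of 2, in which wild type, ARID2 knockout and SMARCA4 knockout carried a control knockdown or a knockdown of SMARCA4, of ARID2 or of both. The labels name the knockdown reagents differently in different fields, so only the word knockdown is used. They do not say that libraries of a group came from separate cultures, and p-values therefore measure only the spread between these libraries.

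The deposited gene tables hold estimated counts (expected counts), which were already whole numbers, so the rounding left them as they were. Every value was at least 1 in both tables, and between 39.94% and 47.17% of genes per knockout library and between 45.54% and 49.13% per double-loss library stood at exactly that minimum. Trimmomatic, Bowtie, Picard and DESeq2 are named per the submitters' processing notes, with the builds GRCh37 and hg19; their versions, the counting tool and the annotation are not given in the sources used here. How reads shared between near-identical genes were counted, and whether counting used the strand, is likewise not given, so values of histone, metallothionein, HLA, protocadherin and actin genes and of overlapping genes are uncertain to that extent. The third deposited table holds quantile-normalized log2 TPM made by the authors, per the labels and its header. It was used only as an alternative, with 71 of its columns. Of the columns of all tables, 8 could not be matched to one labelled sample and were not used.

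Total counts per library ranged from 14917644 to 29993652 in the knockout table (median 20042760) and from 9144150 to 19789622 in the double-loss table (median 13678178). Both tables list 35438 genes under symbols. Because the lowest value is 1, a fold against a group that stood at the minimum in all its libraries is given as a bound, with 3 counts per library as the floor; folds of genes close to the minimum depend on the prior count. Pairs of libraries within a group differed by more than sampling noise, with a lowest chi-square per degree of freedom of 7.986 in the knockout table and 10.05 in the double-loss table.

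Counts were analysed in R 4.3.3 with edgeR 4.0.16: low-count genes were removed with filterByExpr, which left 16159 genes in the knockout table and 14601 in the double-loss table, libraries were scaled with TMM, and a robust quasi-likelihood model was fitted with 1 term per group over all libraries of a table. Each contrast was tested with the quasi-likelihood F-test and adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p of 0.05 and an absolute log2 fold change of at least 1. Log2 fold changes carry their standard errors (SE) and CPM values (counts scaled to the total of their library) their standard deviations (SD), with n = 3 in the knockout table and n = 2 in the double-loss table. Every adjusted p for a gene is from this test. Clones were compared with wild type, the groups of the double-loss table with wild type under the control knockdown, and knockdown with control knockdown inside each knockout. Non-additivity was tested as each double-loss group minus the ARID2 knockout minus the SMARCA4 knockout plus wild type, all on the log2 scale. That contrast treats a knockdown as equal to a knockout, because no group carries the knockdown of 1 gene in wild-type cells.

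The design, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Named genes are called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, ranked by absolute log2 fold change: the first 10 in each direction for SMARCA4, ARID1A, the 3 knockouts with the most called genes besides these and the genes called in all double-loss groups, and the first 2 in each direction elsewhere. Targeted genes, called BAF subunits and the most changed called members of a list are also named, and genes without a symbol are only counted. A few genes that these rules select, 1 of the patterns that were tested and an alternative that rested on it are not reported here. The 32 lists cover A549, HEK293 and fibroblast markers, actin cytoskeleton and SRF targets, class I antigen presentation, BAF subunits, cholesterol synthesis, cytosolic ribosomal proteins, developmental transcription factors, E2F and DNA replication, endoplasmic reticulum stress, epithelial junctions and keratins, extracellular matrix, germline genes, hematopoietic genes, histones, HOX genes, hypoxia and glycolysis, immediate early and AP-1 genes, the integrated stress response, integrins and cadherins, interferon-stimulated genes, mesenchymal genes, metallothioneins, mitosis, MYC-bound growth genes, neuronal genes, NF-kB, oxidative phosphorylation, and p53, TGF-beta and WNT targets. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and adjusted over all lists and comparisons of a table; camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it.

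The similarity of 2 knockouts was the Pearson correlation of their log2 fold changes across genes, which are not independent replicates. PBAF subunits were compared by an exact permutation over all choices of 4 genes and paralogs by 100000 permutations of the gene names. All comparisons of a table share their control libraries. Unchanged groups were therefore simulated against the real controls, 4 times for the knockout table and 20 times for the double-loss table. Such groups show what shared controls and the spread between libraries give, and carry no differences between clones. The steps were tested on simulated data in which 200 genes per group had been changed. Of genes changed 2-fold, 48.2% were called in a clone, 37% in a single knockout of the double-loss table and 13.3% in the test of non-additivity; at 4-fold these shares were 98.6%, 90% and 74.7%, and of the unchanged genes a mean of 3.04, 8 and 8 per group were called.

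Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, a fit of only the groups compared, limma on the deposited log2 values, other correlations and gene sets, and leaving out each library in turn. Added after seeing the data were 1 subtracted from every count, the mean of the other clones as control, offsets for the GC trend of each library, and the class of each library on the first component of the residuals, as a term and within each class. Gene types, chromosomes and GC content came from a reference annotation of another build (GRCh38), so no coordinates are printed. Tables were read with data.table (version 1.17.8) and plots drawn with Python 3.11.15 and matplotlib 3.10.9.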

Results

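The targeted gene's own mRNA was compared first, because a knockout made by a small insertion or deletion can leave a transcript in place. SMARCA4, the main ATPase of the complex, fell in both of its clones, by a log2 fold change of -4.20 (SE 0.148, adjusted p = 1.18e-31) in clone 2878-4 and -4.09 (SE 0.147, adjusted p = 4.54e-31) in clone 2878-6. Its level was 13.82 ± 3.61 and 14.89 ± 1.41 CPM (SD, n = 3) against 254.4 ± 17.5 CPM in wild type. ACTB, the beta-actin gene whose protein is also a BAF subunit, fell from 3795 ± 182 to 115.7 ± 12 CPM (log2 fold change -5.04, SE 0.0965). DPF2 (-3.73), SMARCD1 (-3.07), SMARCC1 (-2.98), BRD7 (-2.59), PHF10 (-2.36), SMARCA2 (-2.15), SMARCD2 (-1.87), ARID1B (-1.66), DPF1 (-1.32) and BCL7B (-1.12) were called lower in their own knockouts as well. ARID1A, the DNA-binding subunit most often mutated in human tumours, fell by 1.24 on the log2 scale in clone 618-3 (92.47 ± 6.45 against 218.4 ± 26.3 CPM) and stayed short of the fold threshold in clone 618-10 (-0.90, SE 0.111, adjusted p = 2.02e-09). DPF3 (-0.88, adjusted p = 0.0137), SMARCC2 (-0.75, 9.19e-08), SMARCD3 (-0.72, 0.000199) and ARID2 (-0.67, 1.38e-05) also passed the test below that threshold. BRD9 (-0.50, adjusted p = 0.147), PBRM1 (-0.19, 0.206), BCL7A (-0.12, 0.486), BCL11A (0.11, 0.783) and BCL11B (0.45, 0.181) did not differ detectably from wild type. In all, 14 of the 24 clones had a called decrease of the targeted mRNA, and in 20 every library lay below every wild-type library, an arrangement that chance gives in 10% of genes for 3 libraries against 3 in either direction. Protein was not analysed here.

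**Figure D1:**
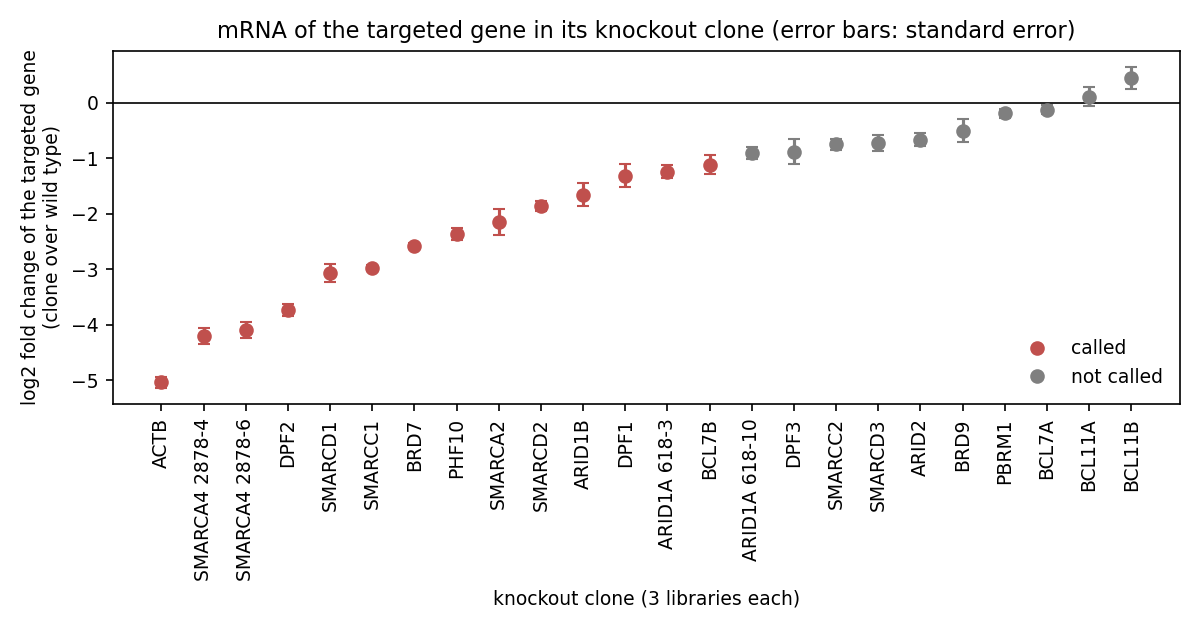
Log2 fold change of the targeted gene in each knockout clone against wild type (n = 3 libraries each), with standard errors; red points passed the test at an absolute log2 fold change of at least 1. ACTB and SMARCA4 lie lowest, and BCL11A and BCL11B lie above 0.

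Loss of SMARCA4 was followed by the largest response of any knockout, with 968 genes called up and 854 down in clone 2878-4 and 893 and 762 in clone 2878-6. PI15, a secreted peptidase inhibitor, rose from 14.34 ± 5.39 CPM in wild type to 2375 ± 346 and 1617 ± 126 CPM (log2 fold changes 7.36 and 6.81, SE 0.224 and 0.219, adjusted p = 1.58e-34 and 6.09e-33). The creatine transporter SLC16A12 rose by 7.74 and 7.36, reaching 35.73 ± 2.51 and 27.55 ± 4.67 CPM from 0.1586 ± 0.0396 CPM. ANKRD1, a target of the YAP coactivator, rose by 6.82 and 7.18, and the matrix protein gene POSTN by 6.81 and 7.18. Further genes at the top in both clones were PDE3A (6.76 and 7.47), the sodium channel gene SCN3A (6.08 and 6.29), the neural adhesion gene CNTN6 (6.08 and 7.04), HSD17B3 (6.06 and 5.70) and MYOF (5.58 and 5.49). NELL1, which encodes a secreted signalling protein, fell from 20.45 ± 2.14 CPM (-8.12 and -8.13), and HCLS1, a cortactin-related gene of blood cells, from 39.92 ± 3.94 CPM (-6.54 and -6.74). The potassium channel gene KCNK2 (-8.89 and -6.61), the smooth-muscle actin gene ACTG2 (-7.97 and -6.42), ZNF385B (-8.43 and -7.58), the surface peptidase gene MME (-7.87 and -7.49), FASTKD2 (-7.37 and -7.68), PGM5 (-7.13 and -6.86), COL11A1 (-6.73 and -7.58) and CYYR1 (-7.23 and -6.69) completed the largest decreases. COL11A1 was lower in 17 of the 24 clones and higher in 7, PGM5 lower in 19, and FASTKD2 lower in 19 and higher in 3. SLC16A12 (12 up, 0 down), ANKRD1 (8 up, 8 down) and POSTN (8 up, 12 down) were called in many clones too. So were CNTN6 (7 up, 5 down), MYOF (11 up, 9 down) and MME (5 up, 7 down). HCLS1 (3 up, 16 down), ACTG2 (1 up, 13 down) and CYYR1 (0 up, 12 down) recurred as well. None of these genes is particular to SMARCA4. The clones shared 728 genes called up and 612 called down, where 53.5 and 40.3 would be expected from the separate counts, and 11 genes were called in opposite directions. Across genes, which are not independent replicates, their fold changes correlated with r = 0.878 and a covariance of 0.727. Both were set against the same wild-type libraries, for which simulated unchanged groups gave a mean r of 0.493 and a covariance of 0.0382.

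Fibroblast markers rose as a group in SMARCA4 loss, with 6 of 7 called up and 1 down in each clone (adjusted p = 1.2e-06 and 1.6e-06; 0.000541 and 0.000585 with an estimated correlation). The receptor gene PDGFRB rose by 4.48 and 3.43, the collagen genes COL3A1 by 4.15 and 4.97 and COL1A1 by 2.41 and 2.11, and THY1 by 2.47 and 2.17, whereas the mesenchymal transcription factor PRRX1 fell to the lowest listed value in every library of both clones. Immediate early genes, which respond to growth-factor signalling, rose with 15 of 32 called up in each clone and 1 and 0 called down (adjusted p = 0.0356 and 0.00275 with an estimated correlation). Among them were SPRY4 (3.23 and 3.84), IER3 (2.88 and 2.84) and ETV4 (2.44 and 2.63). Integrins and cadherins also shifted upward, with 10 up and 4 down, and 9 up and 1 down, of 31 (0.00127 and 4.56e-05 with an estimated correlation), CDH4 rising by 4.55 and 4.45 while CD44 fell (-3.58 and -3.01). The mesenchymal list rose too, with 6 up and 2 down and 8 up and 2 down of 17 (0.0077 and 0.0033 with an estimated correlation), including AXL (3.17 and 3.17). Neuronal genes fell, with 11 and 9 of 25 called down and 3 and 5 up (10 down in clone 2878-6 adjusted over the list alone; 0.000735 and 0.0154 with an estimated correlation). CNTNAP2 (-6.41 and -6.97) and the glutamate receptor genes GRIK2 (-4.57 and -4.58) and GRIA2 (-3.62 and -4.77) led that decrease. Developmental transcription factors fell in 2878-4, with 18 of 66 down and 6 up (19 down adjusted over the list alone; adjusted p = 0.0416 with an estimated correlation), among them POU3F3 (-7.37), FOXA1 (-5.04) and FOXP2 (-4.77). In 2878-6 the same list had 14 down and 6 up and was not called with an estimated correlation (adjusted p = 0.129). The metal-binding metallothioneins fell in both clones, with MT1M (-1.68 and -1.55), MT1E (-1.50 and -1.41) and MT2A (-1.36 and -1.18) called (0.0162 and 0.0258 with an estimated correlation). Targets of actin and SRF rose, with 7 and 8 of 36 called up and 1 down in each (adjusted p = 0.261 and 0.0842 with an estimated correlation), led by TPM2 (4.98 and 4.91) and CNN1 (4.28 and 4.66). Cholesterol synthesis genes had medians of 0.414 and 0.413 with only 1 gene called, down, in each clone (adjusted p = 0.197 and 0.162 with an estimated correlation). TGF-beta targets rose in 2878-6, with 8 up and 3 down of 21 (0.0271 with an estimated correlation), including LEFTY2 (3.29). KIT, the stem-cell factor receptor gene, fell as well (-6.14 and -5.99).

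In ARID1A loss CNTN6 rose by 6.78 in clone 618-10 and 6.75 in 618-3, to 37.63 ± 4.56 and 36.87 ± 0.606 CPM from 0.3241 ± 0.272 CPM (SE 0.357 in each). The water channel gene AQP4 rose by 5.97 and 6.12, to 229.6 ± 18.5 and 253.3 ± 15.2 CPM from 3.535 ± 5.8 CPM. Its wild-type SD exceeds its mean, and it was called higher in 5 of the 24 clones and lower in 19. SCN3A (5.40 and 6.11), PHLDB2 (4.79 and 5.12), NEK3 (4.69 and 4.91), ARHGEF28 (4.68 and 4.82), the activin antagonist FST (4.66 and 4.72), KCTD16 (4.53 and 4.56) and SLC9A2 (4.70 and 4.52) followed. NELL1 was at least 6.98 lower on the log2 scale in 618-10, where it stood at the lowest listed value, and fell by 7.77 in 618-3. MME (-8.03 and -7.43), FASTKD2 (-7.28 and -7.08), COL11A1 (-6.92 and -7.31), the RNA-binding gene CELF2 (-6.42 and -6.04), the GABA receptor gene GABRA5 (-6.23 and -5.98), STAC (-6.06 and -5.80), CYYR1 (-6.93 and -5.37) and LPHN3 (-5.13 and -5.09) fell in both. PXDN fell by 5.72 in 618-10 and was at least 5.01 lower in 618-3. It was called lower in 23 of the 24 clones. GABRA5 (9 up, 13 down), STAC (4 up, 11 down) and LPHN3 (0 up, 14 down) were also called in many clones. The largest adjusted p among the genes named here for ARID1A loss was 3.65e-14. Clone 618-10 had 621 genes called up and 394 down and clone 618-3 had 570 and 416. They shared 430 up and 306 down against 21.9 and 10.1 expected, with 9 genes in opposite directions, and r = 0.828 and a covariance of 0.392 across genes (0.493 and 0.0382 in simulated unchanged groups).

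The list of integrins and cadherins rose in both ARID1A clones, with 7 up and 4 down and 6 up and 3 down of 31 (4 down adjusted over the list alone in 618-3; 0.0101 and 0.0114 with an estimated correlation). PCDH19 (3.43 and 3.38), CDH4 (2.74 and 3.01) and PCDH7 (2.27 and 2.49) rose while CD44 fell (-1.77 and -2.86). Fibroblast markers rose in 618-10, with 3 of 7 up (0.00522 with an estimated correlation), and 2 were up in 618-3 (adjusted p = 0.0742 with an estimated correlation). Among immediate early genes 6 and 8 of 32 were up and none down (7 in 618-10 adjusted over the list alone; adjusted p = 0.103 and 0.0915 with an estimated correlation), including SPRY4 (2.18 and 2.22) and PHLDA1 (1.63 and 2.27). Oxidative phosphorylation genes had medians of 0.171 and 0.139 and MYC-bound growth genes medians of -0.105 and -0.208 without a called member (with an estimated correlation, adjusted p = 0.266 and 0.375, and 0.485 and 0.206). HEK293 markers fell in 618-10, with PAX2 (-2.35) and ZIC2 (-1.37) among 3 called down and PRAME (2.17) the 1 called up of 12 (0.0465 with an estimated correlation; 0.0693 in 618-3). The blood transcription factor gene RUNX1 (-2.38 and -3.44) and KIT (-3.67 and -4.01) fell, whereas TAL1 rose by 1.92 and 2.01.

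Clones of the same gene were not identical. Between the ARID1A clones 132 genes were called higher in 618-10 and 71 higher in 618-3, and between the SMARCA4 clones 127 were higher in 2878-4 and 172 in 2878-6. TAL1, a regulator of blood stem cells, was called lower in SMARCA4 clone 2878-4 (-2.39) and higher in 2878-6 (1.76). Every other gene had 1 clone, so an effect of its loss cannot be told apart from other features of that clone. In what follows, raised and lowered describe the clone against wild type.

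ARID1B, the paralog of ARID1A, gave 1108 called genes, 559 of them up. The lactate transporter gene SLC16A7 (5.70), CPED1 (5.53), the metabolic coactivator PPARGC1A (5.37), COLEC11 (5.22), ARHGEF28 (4.88), CNTN1 (4.80), the lipase gene LPL (4.68), RENBP (4.67) and the TGF-beta coreceptor ENG (4.34) rose most; ENG was called higher in 2 clones and lower in 22. CYYR1 (-7.20), COL11A1 (-7.15), SLC17A9 (-6.72), OLFM3 (-6.53), SLC16A14 (-6.47), NELL1 (-6.37), WBP5 (-6.10), PXDN (-6.08), ZNF256 (-5.81) and EFS (-5.54) fell most, all with adjusted p of at most 7.64e-15. Extracellular matrix genes fell, with 9 of 41 down and 1 up (10 down adjusted over the list alone; 0.00257 with an estimated correlation), led by SPARC (-5.24), THBS1 (-3.64) and LAMB1 (-3.55). Fibroblast markers fell with 4 of 7 called, among them PDGFRA (-4.40) and POSTN (-3.48; 0.00456 with an estimated correlation), and so did mesenchymal genes, with 5 of 17 down (6 adjusted over the list alone), including PRRX1 (-3.87). Actin and SRF targets fell with 6 of 36 down (0.0142 with an estimated correlation), among them ACTG2 (-4.11), CYR61 (-3.10) and CTGF (-1.98). Histone genes (6 of 19 down, 7 adjusted over the list alone; HIST1H2AC -2.18, HIST1H4H -2.00), mitotic genes (none of 29 called, median -0.292), TGF-beta targets (3 of 21 down, 5 adjusted over the list alone; ID1 -1.92) and metallothioneins (MT2A alone of 5) also moved down, with adjusted p of 0.00203, 0.0144, 0.00909 and 0.00695 with an estimated correlation. The integrated stress response rose with 4 of 30 up (5 adjusted over the list alone; 0.0103 with an estimated correlation), NUPR1 by 4.30, CHAC1 by 1.70 and ASNS by 1.32. Cholesterol synthesis rose with NSDHL (1.37) and INSIG1 (1.33) among the called genes (0.0167). Class I antigen presentation (PSMB9 2.81, NLRC5 1.98; 0.00909) and interferon-stimulated genes (7 of 30 up and 2 down, with SAMD9 3.30 and MX1 1.65; 0.0121) rose as well, all values with an estimated correlation.

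BCL7B loss gave 508 genes up and 481 down and lowered matrix genes in company with a gain of antigen-presentation genes. The GTPase regulator TIAM1 rose by 6.12 (40.09 ± 2.69 against 0.5847 CPM), the endoderm factor FOXA2 by 6.04, RNF128 by 5.78, MKX by 5.75, SLC16A7 by 5.33, CNTN1 by 5.22, CHFR by 4.95, CHI3L2 by 4.90, RIMS2 by 4.69 and KIAA1324L by 4.52. BST2, which tethers budding viruses, fell by 7.01 (SE 0.161, adjusted p = 9.17e-41) from 211.1 ± 15.7 to 1.62 ± 0.768 CPM. COL11A1 (-6.74), SLC43A3 (-6.40), RELN (-5.98), SETBP1 (-5.76), ZNF256 (-5.75), PGM5 (-5.42), CNTNAP2 (-5.09), ZNF440 (-4.91) and MPDZ (-4.79) followed. Extracellular matrix genes fell with 12 of 41 down and 2 up (0.00121 with an estimated correlation), led by COL4A6 (-3.68), VCAN (-2.88) and SPARC (-2.65), and fibroblast markers with 4 of 7 down (0.0142), led by PDGFRA (-4.25). Class I genes rose with 4 of 15 up (0.000542 with an estimated correlation): PSMB8 by 3.55, NLRC5 by 2.52, PSMB9 by 2.19 and HLA-B by 1.07. Hematopoietic genes rose with CD38 (3.05), LCP1 (1.99) and TAL1 (1.85) of 16 called (4 adjusted over the list alone; 0.0154 with an estimated correlation).

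SMARCC2, a scaffold subunit and the paralog of SMARCC1, gave 531 genes up and 517 down. The elastic-fibre gene MFAP2 (4.19), GABRA5 (3.55), CSMD1 (3.48), the synaptic genes RIMS2 (3.20) and SYT1 (3.05), THSD7B (3.11), VSTM4 (2.73), GALNT5 (2.71), SLIT3 (2.63) and MGARP (2.63) rose most. DNAJC15 was at least 6.35 lower and VIT at least 5.86 lower, both at the lowest listed value in every library. COL11A1 (-7.74), WBP5 (-7.71), the matrix gene SPARC (-7.12, from 135.8 ± 8.04 to 0.9172 ± 0.368 CPM), FASTKD2 (-6.60), EFS (-6.54), PI15 (-6.41), PAK6 (-5.82) and THBS1 (-5.70) fell. Actin and SRF targets fell with 8 of 36 down (0.0301 with an estimated correlation), led by CYR61 (-3.74) and CALD1 (-2.79), and fibroblast markers with 4 of 7 down (0.0407), led by POSTN (-3.68). MYB (2.48) and TAL1 (1.61) were among 4 of 16 hematopoietic genes called up (0.0391). Matrix genes had 12 of 41 down and 1 up (adjusted p = 0.237 with an estimated correlation). Endoplasmic reticulum stress genes had a median of -0.331 and none called (adjusted p = 0.344 with an estimated correlation). Fold changes in this clone rose with the GC content of the gene (Spearman rho 0.456, against -0.0965 to 0.207 in the other clones), and with offsets for that trend 793 genes were called in place of 935 among the 14508 genes with a GC value.

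**Figure D2:**
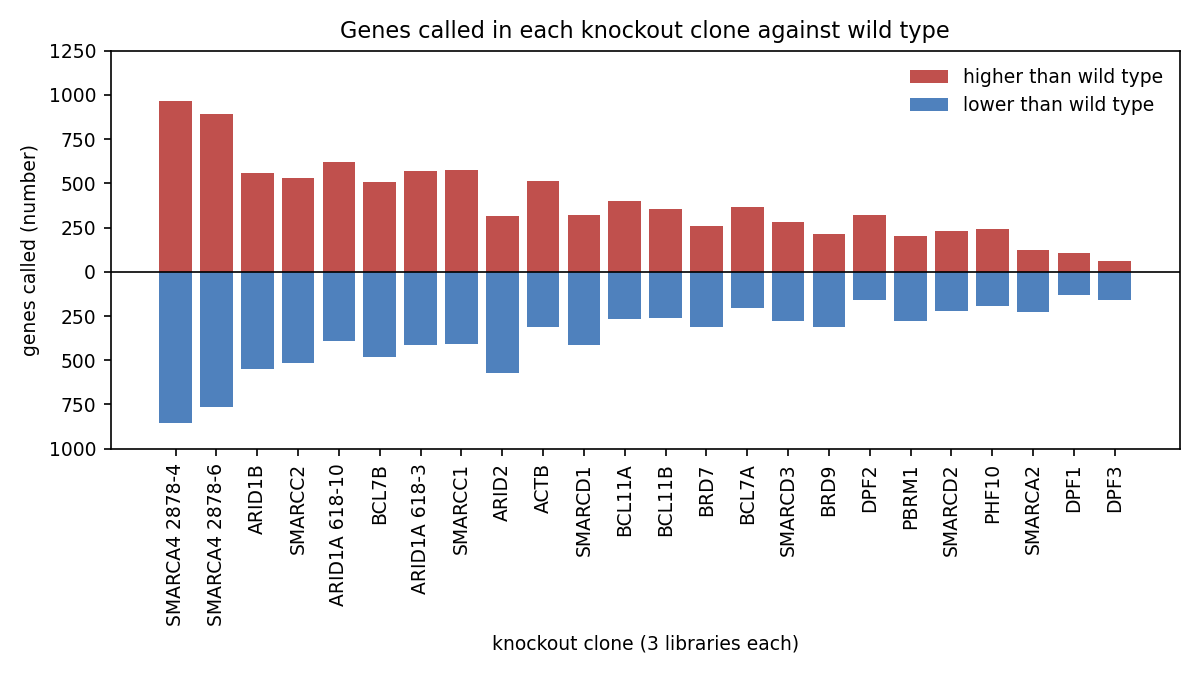
Number of genes called higher (red) and lower (blue) than wild type in each knockout clone (n = 3 libraries each). The SMARCA4 clones had the most called genes, 1822 and 1655, and DPF3 the fewest, 217.

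Among the other clones, ACTB loss (513 up, 311 down) raised the genes of the actin cytoskeleton that SRF controls. ACTA2 rose by 6.17, TPM2 by 5.51, CNN1 by 5.10 and ACTG2 by 4.45, with 15 of 36 called up and 1 down (adjusted p = 9.65e-30; 1.09e-05 with an estimated correlation). The protease inhibitor gene A2M (8.06) and CDH13 (7.62) rose most, and HCLS1 (-7.98) and WBP5 (-6.91) fell most. Class I genes (PSMB8 4.73, NLRC5 3.45), mesenchymal genes (THY1 7.10, MMP2 2.70) and immediate early genes (SPRY4 2.69) also rose and neuronal genes (GRIA2 -4.31, CNTN1 -3.39) fell, with adjusted p of 4.42e-05, 0.00522, 0.00629 and 0.0093 with an estimated correlation.

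PBAF is the form of the complex that holds ARID2, PBRM1, BRD7 and PHF10. ARID2 loss (318 up, 575 down) lowered class I antigen presentation, with 5 of 15 down (0.00202 with an estimated correlation), among them ERAP2 (-2.45), NLRC5 (-2.12), PSMB8 (-1.89) and HLA-B (-1.43). Interferon-stimulated genes fell with 7 of 30 (8 adjusted over the list alone; 0.00419), led by CMPK2 (-3.20) and OAS2 (-2.39), and so did metallothioneins (MT1M -3.81, MT1F -1.30; 0.00275). CNTN6 (4.59) and NDST4 (4.57) rose most and COL11A1 (-7.36) and CNTNAP2 (at least 5.91 lower) fell most. The clone labelled as PBRM1 knockout, whose targeted mRNA was not detectably lower (202 up, 277 down), had higher MFAP2 (3.81) and GABRA5 (3.75) and lower HCLS1 (-8.43) and COL11A1 (-7.47). BRD7 loss (261 up, 313 down) raised 6 of 19 histone genes, among them HIST1H2AC (1.34) and HIST1H2BJ (1.29; 0.0153 with an estimated correlation), and lowered PAX2 (-3.64); RHBDD1 (6.93) and KIAA1324L (4.97) led the increases and S100A6 (-7.14) and COL11A1 (-7.04) the decreases. The PHF10 clone (242 up, 191 down) had higher SHISA2 (4.63) and THSD7B (3.59) and lower SLC7A3 (-8.22). Across the clones SHISA2 was called up in 3 and down in 12, and THSD7B up in 10 and down in 11. The interferon genes OAS2 (-2.89), IFIH1 (-2.14) and BST2 (-2.01) were lower in the PHF10 clone (adjusted p = 0.0307 for the list by camera with an estimated correlation).

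Neuronal genes were lower in the clones labelled as knockouts of BRD9, a subunit of the noncanonical form of the complex, and of SMARCD1, each with 10 of 25 down and 1 up (1.94e-05 and 0.00016 with an estimated correlation). The BRD9 clone, whose targeted mRNA was not detectably lower (216 up, 314 down), had lower KIF5A (-3.73) and GAP43 (-3.60), and GABRQ (4.73), GSTM2 (4.16), SLC16A14 (-7.50) and COL11A1 (-7.30) changed most. SMARCD1 loss (324 up, 415 down) lowered CNTNAP2 (-4.89), GAP43 (-4.12) and PDGFRA (-5.90), raised KIF5A (3.71), and had GJA1 (6.12), RHOD (5.13) and SLC7A3 (-8.79) among its most changed genes. Among its relatives, SMARCD2 loss (232 up, 220 down) raised SCARA3 (6.55), C1orf85 (6.10) and COL3A1 (4.11) and lowered COL11A1 (-7.61), CNTNAP2 (-6.70) and TAL1 (-4.65). The clone labelled as SMARCD3 knockout (282 up, 278 down), whose targeted mRNA stayed short of the fold threshold (-0.72), had higher RHOD (5.60) and NLGN4X (5.60) and lower SLC7A3 (-8.75). RHOD and NLGN4X also led the increases in the BCL11B clone, whose targeted mRNA was not detectably lower.

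SMARCC1 loss (576 up, 409 down) raised immediate early genes, with 11 of 32 up (0.00973 with an estimated correlation), EGR2 by 3.16 and PHLDA1 by 2.73. Hematopoietic genes fell through TAL1 (-4.77), KIT (-3.81) and RUNX1 (-2.18; 0.0101), and CNTN6 (6.69) and PIP5K1B (5.76) rose most. SMARCA2 loss (125 up, 229 down) lowered matrix genes, 8 of 41 (0.0021), and fibroblast markers, among them POSTN (-3.42), COL3A1 (-3.19) and THY1 (-2.84; 0.00038), and raised interferon genes such as OAS2 (2.32) and IFIH1 (1.53; 0.000542); FUT9 (4.83), PCDHB2 (4.38), COL11A1 (-7.48) and SLC16A14 (-6.84) changed most. The clone labelled as BCL7A knockout (368 up, 204 down), whose targeted mRNA was not detectably lower, had higher matrix genes, 7 of 41 with 3 down (0.00695), including POSTN (4.23) and VCAN (3.16). OAS2 was lower there (-3.17), and AEBP1 (7.45), RHOD (5.54) and SLC7A3 (-8.29) were among its most changed genes. The clones labelled as BCL11A knockout (400 up, 269 down) and BCL11B knockout (354 up, 261 down), in which the targeted mRNA was not detectably lower, had PDGFRA lower (-4.62 and -4.93) and PRRX1 at the lowest listed value. TLX3 (5.46) and RHOD (5.32) led the increases in the BCL11A clone and NLGN4X (7.27) and RHOD (5.49) in the BCL11B clone. RHOD was called higher in 8 clones and lower in 13.

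Of the DPF genes, which encode histone-reading subunits, DPF2 (323 up, 159 down) raised integrins and cadherins when lost, with 7 of 31 up (8 adjusted over the list alone; 8.55e-05 with an estimated correlation), NCAM2 by 1.93 and L1CAM by 1.80. Its mesenchymal genes rose with MMP2 (3.38) while PRRX1 fell to the lowest listed value, and FOXP2 (3.55), COL9A1 (3.50), MARC1 (-8.17) and COL11A1 (-7.24) changed most. DPF1 loss (108 up, 133 down) lowered neuronal genes such as KIF5A (-2.95) but raised GRIA2 (3.08; 0.00478), and changed HOXC9 (4.26), LTBR (3.16), COL11A1 (-7.37) and FASTKD2 (-6.43) most. DPF3 loss (59 up, 158 down) lowered CNTN1 (-3.66) and KIF5A (-2.59) among the neuronal genes (3.33e-05); ALDH1A2 (4.69) and THSD7B (3.19) rose and COL11A1 (-7.55) and PXDN (at least 5.04 lower) fell.

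Across the 24 clones 217 to 1822 genes were called (median 642), 4087 genes in at least 1 clone and 8 in all of them. The same genes recurred: 379 were called in at least 12 clones, of which 47 were called up and 137 down in at least 12. RGS14, which restrains G-protein signalling, rose in 19 clones and RASGEF1A in 18, without a call in the other direction, whereas PRRX1 fell in 22 and TCEAL8 in 23 (1 up). WBP5 (6 up, 17 down), EFS (5 up, 18 down), CNTNAP2 (1 up, 18 down), HCLS1 (3 up, 16 down) and CYYR1 (0 up, 12 down) recurred too. Genes called in one direction in at least 12 clones made up 8.4% to 42.4% of the calls of a clone (median 20.9%). All clones share 3 wild-type libraries. Simulated unchanged groups against those libraries gave a mean of 0.0104 called genes and no gene in 12 clones. That covers only the shared wild type, because unchanged groups carry no differences between clones, and it is no baseline for recurrence across clones.

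Subunits of the complex other than the targeted gene had 4 calls up and 5 down among 696 tests (the same adjusted over the list alone). Without the limit on the fold change 26 tests were up and 69 down at an adjusted p under 0.05, of which 11 and 12 of 29 were down in SMARCA4 clones 2878-4 and 2878-6. GLTSCR1L was higher in the BRD9 (1.86), SMARCD1 (1.93) and BCL7B (1.05) clones, and SMARCA2 in SMARCA4 clone 2878-4 (1.16). BCL11A (-4.08 and -3.34) and BCL11B (-4.64 and -3.81) fell in both SMARCA4 clones, and BCL11B was lower in the BCL7A clone (-1.47).

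Of 768 tests of a list in a clone 207 were called, 93 up and 114 down, and 100 with an estimated correlation. Fibroblast markers were called up in 8 clones and down in 10, mesenchymal genes 6 and 9, extracellular matrix 3 and 9, integrins and cadherins 8 and 1, immediate early genes 11 and 6, and actin and SRF targets 6 and 7. Neuronal genes were called in 8 clones, always down. MYC-bound growth genes were called in 9, E2F and DNA replication in 6, mitosis in 2, WNT targets in 2 and BAF subunits in 3, all down. The BAF list kept the targeted gene of each clone, so its calls do not describe the other subunits alone. Metallothioneins were called up in 2 and down in 8, interferon-stimulated genes 4 and 4, class I genes 4 and 2, the integrated stress response 8 and 3, cholesterol synthesis 6 and 4, and hematopoietic genes 4 and 2. HEK293 markers were called 3 up and 4 down, epithelial junctions and keratins 3 and 3, ribosomal proteins 3 and 3, developmental transcription factors 1 and 3, histones 1 and 3, oxidative phosphorylation 4 and 1, endoplasmic reticulum stress 1 and 1, and TGF-beta targets 1 and 1. A549 markers, HOX genes and hypoxia genes were called up in 2 clones each. Germline genes, NF-kB targets and p53 targets were called in none by camera, with smallest adjusted p of 0.329, 0.242 and 0.0545. With an estimated correlation mesenchymal genes were called in 15 clones, fibroblast markers in 14, integrins and cadherins in 9, neuronal genes in 8, interferon-stimulated genes in 7, and hematopoietic genes in 6. Matrix, immediate early, class I, metallothionein and HEK293 lists were called in 5 each, actin and SRF targets in 4, histones in 3, and TGF-beta targets and BAF subunits in 2 each. Cholesterol synthesis, the integrated stress response, developmental transcription factors, epithelial genes and mitosis were called in 1 each. The MYC-bound, E2F, WNT, A549, HOX, hypoxia, ribosomal, oxidative phosphorylation and endoplasmic reticulum stress lists were then called in none.

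On average over 6 pairs, the clones labelled as knockouts of PBAF subunits had more similar fold changes to each other than to the other knockouts. Each of these genes had 1 clone, so the permutation of gene names does not separate the lost subunit from the clone. PBRM1 mRNA was not detectably lower in its clone (-0.19, adjusted p = 0.206). Their mean correlation across genes was 0.44 against 0.224 for the pairs of a PBAF subunit and a gene outside that set (difference 0.217, exact permutation p = 0.0067 over 7315 choices, two-sided). ARID2 and PBRM1 reached 0.613, BRD7 and PBRM1 0.517, ARID2 and BRD7 0.486, PBRM1 and PHF10 0.422, ARID2 and PHF10 0.319, and BRD7 and PHF10 0.285. The mean did not hold for each gene. PHF10 was closer to BCL7A (0.498) than to any PBAF subunit, and ARID2 with SMARCA4, outside the set, reached 0.442. The mean covariance of the PBAF pairs was 0.136, against 0.0841 over all 231 pairs and 0.0382 for simulated unchanged groups, which share the same wild type and correlate with r = 0.493. Paralogs were not closer than other pairs, with 0.286 over 11 pairs against 0.25 (difference 0.0359, p = 0.394 by 100000 permutations, two-sided). The paralogs ranged from -0.0466 (SMARCD2 and SMARCD3) to 0.793 (BCL11A and BCL11B), with 0.639 for SMARCD1 and SMARCD3 and 0.0631 for the ATPases SMARCA2 and SMARCA4. Of all pairs BCL11B and SMARCD3 correlated most (0.802), and BCL11A and SMARCD3 reached 0.71, ARID1A and SMARCA4 0.666 and BRD9 and SMARCD1 0.467. In the BCL11A and BCL11B clones the targeted mRNA was not detectably lower, so high correlations also arose where the mRNA shows no loss.

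In the double-loss table SMARCA4 mRNA was 313.4 ± 16.1 CPM (SD, n = 2) in wild type with the control knockdown and fell in each group with the knockout or with the knockdown in ARID2 knockout. The log2 fold changes were -3.66 (adjusted p = 0.000916) in the knockout, -3.84 (0.000596) with ARID2 knockdown added, and -4.02 (0.000826) for the knockdown in ARID2 knockout. In wild type with both knockdowns it was 87.63 ± 62.7 CPM (-1.84, SE 0.463, adjusted p = 0.104), with 1 library at 43.3 CPM and the other at 132 CPM; with the replicate number as a block it was called (-1.97, adjusted p = 0.0182). ARID2 mRNA did not differ detectably in any group: -0.36 (adjusted p = 0.882) in its knockout, -0.15 (0.791) in that knockout with SMARCA4 knockdown, -0.60 (0.262) for the knockdown in SMARCA4 knockout, and -0.46 (0.584) with both knockdowns in wild type. In SMARCA4 knockout alone ARID2 stood at 0.06, and SMARCA4 in ARID2 knockout alone at 0.02.

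The 3 groups whose labels name the loss of ARID2 and SMARCA4 shared a small set of genes, 30 up and 27 down in all 3, where 0.0788 and 0.0837 would be expected and simulated unchanged groups shared none. The set held 281 genes with the replicate block, 147 by DESeq2 and 0 in fits of only the groups compared. GDF3, a TGF-beta family ligand of pluripotent cells, rose by 2.97 in ARID2 knockout with SMARCA4 knockdown, 4.56 in SMARCA4 knockout with ARID2 knockdown and 2.30 in wild type with both knockdowns. The linker-histone gene HIST1H1C rose by 2.86, 2.71 and 2.12, from 2.978 ± 0.0896 CPM to 21.63 ± 6.01, 19.55 ± 2.79 and 13 ± 0.465 CPM. TLE1 (2.23, 2.51, 2.56), ESRRG (2.16, 3.58, 2.40), RFX4 (3.23, 2.98, 2.08), DOCK4 (2.82, 2.00, 2.22), ADAMTS9 (2.02, 2.96, 1.93), IRX6 (3.45, 1.91, 2.60) and the prostaglandin receptor gene PTGER3 (1.81, 2.88, 1.87) rose as well, in the same order of groups. The cell-cycle gene CCND2 (-2.50, -4.57, -3.13), HCLS1 (-7.61, -7.68, -2.48) and KIT (-4.36, -6.23, -2.37) fell. IFITM1 was at least 4.99 lower in the first group and fell in the others (-5.81 and -3.88), and CNTNAP2 was at least 5.4 lower in the first and fell in the others (-6.24 and -1.89). NPNT (-6.04, -5.36, -3.07), BTBD11 (-4.24, -2.29, -4.44), PPP1R14C (-3.48, -3.17, -2.23), ZNF660 (-4.36, -3.81, -2.12) and KIAA1644 (-2.22, -1.88, -1.97) fell as well. These calls rest on wild type with both knockdowns, where 82 genes were called (43 up, 39 down; 402 with the replicate block), 0 without its replicate 1 and 14 without replicate 2 of the control, which leave 0 and 11 genes called in all 3. Without any 1 library of the SMARCA4 knockout groups it was between 43 and 48, with 27 to 32 genes in all 3.

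**Figure D3:**
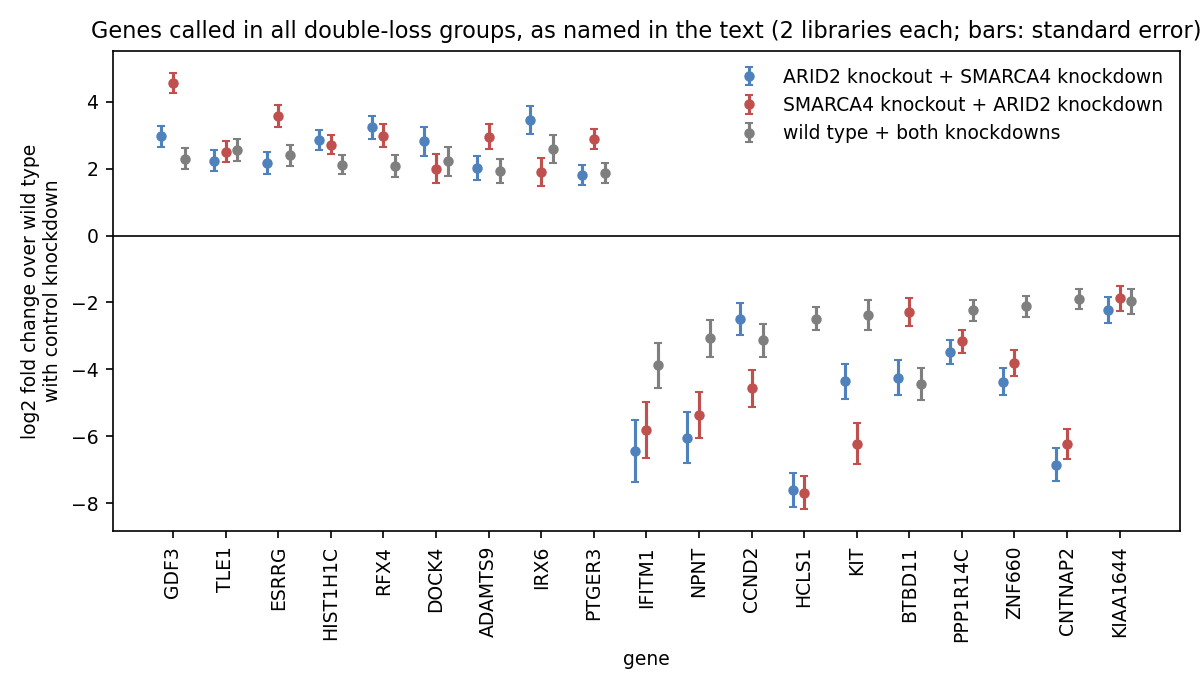
Log2 fold change with standard error of the genes named above that were called in all double-loss groups, against wild type with control knockdown (n = 2 libraries each). Colours mark the group, 9 genes lie above 0 and 10 below in every group, and IFITM1 and CNTNAP2 in ARID2 knockout with SMARCA4 knockdown are fitted values at the lowest listed count.

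ARID2 knockout with SMARCA4 knockdown had 616 genes up and 744 down and SMARCA4 knockout with ARID2 knockdown 634 and 615. CNTN6 (at least 5.07 higher) and MYOF (5.38, 12.6 ± 16.8 CPM) led the increases in the first, and GALNT5 (-7.85) and HCLS1 the decreases. AQP4 (9.06), PDE3A (at least 7.49 higher), NELL1 (-7.90) and KCNK2 (-7.82) led in the second, and UNC5C (3.34), B3GAT2 (2.90), BTBD11 and HOXB9 (-4.13) in wild type with both knockdowns. Without its own replicate 1 the first count was 691, without replicate 2 of the control 716, and the second count was 710 and 788 without its replicates 1 and 2.

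Histone genes, whose mRNAs mostly lack a poly-A tail, rose in the 3 groups labelled with both losses, with 9, 10 and 3 of 14 called up (10 in each adjusted over the list alone, medians 2.01, 2.13 and 1.62, adjusted p = 0.307, 0.289 and 0.289 by camera with an estimated correlation). The rise was not limited to these groups, since the list was called up in 9 of 10 comparisons, with a lowest median of 0.193. HIST1H4H rose by 3.39 in ARID2 knockout with SMARCA4 knockdown and HIST1H2AC by 3.25 in SMARCA4 knockout with ARID2 knockdown. Immediate early genes rose with 9 and 11 up in those groups (12 and 13 adjusted over the list alone; adjusted p = 0.596 and 0.486 with an estimated correlation), SPRY4 by 3.78 and 4.87. WNT targets fell with 3 and 4 of 16 called (4 and 4 adjusted over the list alone, 0.446 and 0.486 with an estimated correlation), led by SFRP1 (-5.42 and -3.84) and LEF1 (-3.27 and -3.46). Immediate early genes had also risen in both SMARCA4 clones of the knockout table. SFRP1 was also called lower in ARID2 knockout with the control knockdown (-3.335). Neither change was thus limited to groups labelled with both losses. In ARID2 knockout with SMARCA4 knockdown cholesterol synthesis fell with 6 of 24 (7 adjusted over the list alone; 0.72 with an estimated correlation), including INSIG1 (-1.68) and MSMO1 (-1.50), and so did hematopoietic genes with KIT, TAL1 (-3.64) and MYB (-1.68; 0.486). SMARCA4 knockout with ARID2 knockdown had higher TGF-beta targets, with 8 of 20 up and 2 down (0.629), LEFTY2 rising by 6.33. Fibroblast markers had 3 of 7 up and 1 down there (0.307), POSTN rising by 8.88 and COL3A1 by 7.10. POSTN (8.47), COL3A1 (3.59) and the TGF-beta target CTGF (1.78) were also called higher in SMARCA4 knockout with the control knockdown. For POSTN, COL3A1 and CTGF the rise was thus not limited to groups labelled with both losses.

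Of 310 tests of a list here, 99 were called, 51 up and 48 down, and 0 by camera with an estimated correlation; fry called 48. Histones were called up in 9 comparisons, immediate early genes in 6 and down in 1, integrins and cadherins and TGF-beta targets up in 4, neuronal genes 4 up and 1 down, actin and SRF targets 3 up, and class I genes, interferon-stimulated genes and metallothioneins 3 up and 1 down each. WNT targets were called 3 up and 5 down, ribosomal proteins, hypoxia and mitosis 5 down, the integrated stress response 4 down, cholesterol synthesis and hematopoietic genes 3 down, and E2F and epithelial genes 2 down. Developmental transcription factors, fibroblast markers and mesenchymal genes were called 2 up and 2 down each, matrix genes 1 up and 2 down, HOX genes 1 and 1, and oxidative phosphorylation 1 up. A549 markers (smallest adjusted p 0.135), BAF subunits (0.261), endoplasmic reticulum stress (0.246), HEK293 markers (0.125), MYC-bound growth genes (0.0639), NF-kB (0.28) and p53 targets (0.262) were called in none by camera, and germline genes had too few tested members.

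The single knockouts were measured in both tables. The labels give no clone number for the double-loss libraries, so the same clones may have been used in both. Agreement between the tables can therefore hold features of a clone as well as effects of the loss. In the double-loss table SMARCA4 knockout (487 up, 402 down) raised the pluripotency gene LIN28A by 8.76, from 0.214 to 98.78 ± 7.75 CPM, and PDE3A by at least 7.12, and lowered NELL1 (-8.12) and CHL1 (at least 6.39 lower). Wild type of the knockout table had LIN28A at 36.08 ± 5.5 CPM, and its SMARCA4 clones raised it by 3.19 and 3.36. The larger rise here goes with a control that nearly lacks the transcript. Across the clones of the knockout table LIN28A was called higher in 9 and lower in 10 (-5.69 to 3.36), so its change is not particular to SMARCA4. ARID2 knockout called 60 genes up and 169 down (111 and 286 with the replicate block, 26 and 88 in a fit of only the groups compared). It raised SLITRK1 (5.14) and PPP2R2B (4.76) and lowered GALNT5 (-8.03) and HCLS1 (-7.70). Class I genes were down through PSMB8 (-3.55) and ERAP2 (-3.05, with adjusted p = 0.289 for the list by camera with an estimated correlation). Of 1193 genes called in both SMARCA4 clones of the first table with the same sign, 97% had that sign here. Across genes r was 0.814 against the mean of the clones, and 628 genes were called in both tables. From the calls of 1 clone alone, 91.4% of 1584 genes (2878-4) and 96.2% of 1462 (2878-6) had the same sign. For ARID2, which has 1 clone, it was 91.7% of 784, r = 0.666 and 191 genes. Over all 14574 genes tested in both tables the sign agreed for 72.6% with SMARCA4 and 58.1% with ARID2. Called genes of ARID2 knockout numbered 91 and 82 without its replicates 1 and 2 and 142 without replicate 2 of the control.

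Knockdown of SMARCA4 inside ARID2 knockout raised 248 genes and lowered 173 (407 and 393 with the replicate block), with MYOF (5.91, 12.6 ± 16.8 CPM against 0.2022 CPM), EMP1 (3.98), SLC26A7 (-4.58) and MME (-4.38) changing most. Immediate early genes rose with 9 of the list called (12 adjusted over the list alone; 0.446 with an estimated correlation), and TGF-beta targets with 5 (7 adjusted over the list alone; 0.662). This count was 63 and 90 without replicates 2 and 1 of the ARID2 knockout with control knockdown, 97 and 864 without replicates 1 and 2 of the group with SMARCA4 knockdown, and 260 without either replicate of SMARCA4 knockout with ARID2 knockdown. Knockdown of ARID2 inside SMARCA4 knockout called 3 genes up and 0 down by edgeR, with 900 genes at an unadjusted p under 0.05 and 13 called by DESeq2; without any 1 library of either group it called 0. With the replicate number as a block this knockdown of ARID2 called 19 genes. Of the 3 genes called without the block COL3A1 was the named one, at 16.35 ± 3.57 against 1.429 CPM (log2 fold change 3.51, adjusted p = 0.0183).

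Non-additivity asks whether a group labelled with both losses differs from the sum of the single knockouts on the log2 scale. HCLS1 lay 7.59 and 7.52 above the sum in ARID2 knockout with SMARCA4 knockdown and in SMARCA4 knockout with ARID2 knockdown, as it was already near the lowest listed value in each single knockout. HRASLS5 (7.57) lay above it in the first and GALNT5 (7.92) in the second, whereas the Hedgehog-pathway regulator KCTD11 (-4.96 and -4.31), KRT8 (-4.04, first group) and LIN28A (-3.84, second group) lay below it. The first group had 73 genes above and 82 below the sum (166 and 220 with the replicate block, 156 and 183 by DESeq2, 40 and 31 in a fit of only the groups compared). The second had 25 above and 16 below (49 and 31, 62 and 34, and 19 and 11 in the same order). Of the 73 and 25 above, 66 and 25 had been called lower in at least 1 single knockout, 18 and 12 in both. Of the 82 and 16 below, 63 and 14 had been called higher in at least 1. In wild type with both knockdowns, where SMARCA4 mRNA fell less than in the knockout, 258 genes were above and 248 below, led by COL11A1, FASTKD2 (13.10), CPLX1 (-4.08) and GDF3 (-3.93). COL11A1 was at 24.67 ± 4.57 CPM there against 12.19 ± 2.95 CPM in the control, and had fallen in both single knockouts (-6.25 in ARID2). In SMARCA4 knockout it stood at the lowest listed value, so its distance above the sum is not given. Neuronal genes lay above the sum in all 3 groups, with 2, 1 and 6 of 21 called (6, 1 and 9 adjusted over the list alone, adjusted p = 0.307, 0.34 and 0.428 by camera with an estimated correlation). The floor limits this list as well. CNTNAP2 stood at 0.1467 CPM in ARID2 knockout against 10.92 CPM in the control. A gene so near the lowest listed value cannot reach the sum where the other knockout lowers it too. The first count, 155 genes, was 65 and 79 without replicates 1 and 2 of the ARID2 knockout, 69 without either of the SMARCA4 knockout, 87 without replicate 1 of the control and 316 without replicate 2 of the group itself. The second, 41 genes, was 17 to 27 without any 1 library it uses, and the last, 506 genes, 327 without replicate 2 of the ARID2 knockout.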

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

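The tests of GC content and of the wild-type libraries were chosen only after the result was seen; those of GC content as the whole cause and of other splits were planned before their values were known.

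The clones of 1 gene differed from each other by direct test in 203 genes for ARID1A and 299 for SMARCA4, which stood out because clones carry the same label apart from the clone number. SMARCA4 knockdown in ARID2 knockout departed from the sum of the single knockouts in 155 genes, ARID2 knockdown in SMARCA4 knockout in 41, and both knockdowns in wild type in 506, each by a test of the difference itself.

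The first pattern is that SMARCC2 fold changes followed the GC content of genes, with Spearman's rho 0.456 across 14508 genes, which are not independent replicates, and no other clone above 0.207. GC bias in these 3 libraries is a candidate source of part of the changes. With the GC trend of each library as an offset 793 genes were called instead of 935 among the genes with a GC value (1048 over all genes), while the other clones had a median of 568 (204 to 1712), so the trend as the whole cause is argued against; SMARCC2 then ranked 9 by its count. Loss of the subunit itself, the biological explanation that the design offers, was not tested apart from the clone. These libraries are also numbered among the samples of the double-loss table, apart from the wild type and the other clones of their own table, and carry no clone number, so a separate submission cannot be told from the knockout.

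The second pattern is that 47 genes were called up and 137 down in at least 12 clones, although the clones lack different subunits. If the wild-type libraries of this table alone stood apart, the genes would not recur in the other table, which has its own control. Of 110 such genes picked without the ARID2 and SMARCA4 clones 96 were tested there, and their median change in the same direction was 1.6 in ARID2 knockout (68.8% in that direction) and 2 in SMARCA4 knockout (72.9%). This argues against the wild-type libraries of 1 table; cloning itself, a shift in the wild-type stock common to both tables, and a shared effect of losing any subunit may each remain. In wild type with both knockdowns the median was 0.0987 (54.2% in that direction).

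Other splits of the libraries were counted for each comparison of 3 libraries with 3. With 10 splits the share is never under 0.1, so the splits are too few; in all 26 comparisons only 1 split, the real one, gave as many genes, with 114 to 1617 genes in the real splits and 0 to 51 as the highest other, and the real count was at least 2.73 times the highest other. For the genes called in both ARID1A clones 1 of 100 splits of the 9 libraries called as many, the real one with 640 genes, against 27 as the highest other. For SMARCA4 3 of 100 splits called as many, the real one with 1247 and the highest other with 1274. These 3 keep the wild-type libraries together and only mix the clones, and the highest with wild type divided was 58. Splits of that kind can call as many genes, so the share depends on which were drawn. The splits ask only whether wild type differs from the clones in these libraries. They do not exclude chance differences between cultures. Groups of 2 in the double-loss table were not split.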

How the results depend on the processing

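The tests with the other clones as control, with GC offsets, with library classes and with 1 subtracted from each count were chosen only after the result was seen, and so were the fit of only the groups compared for the ARID1A and SMARCA4 clone pairs and for all double-loss groups, and limma for the clone pairs; the others were planned. Of 432 values of 47 results under another setting 379 kept their direction and their side of the threshold, or for counts lay within 1.5 times the reported one; of 318 values with a library left out 274 did. RLE size factors, no low-count filter, limma on the deposited log2 values, GC offsets and the class as a term changed none of the results they were run for (41, 41, 27, 30 and 27). Of 1705 values of named and targeted genes 1691 stayed on their side, 13 lost their call, none changed sign, and SMARCA4 in wild type with both knockdowns gained it with the replicate block (-1.97, adjusted p = 0.0182). The cause was not tested, except that fits of fewer libraries or classes hold fewer samples. With groups of 2 libraries the lone library left is assumed to vary like the other groups, and a 2-fold change is found in 37% of cases. The limit set for pairing was a correlation of deviations above 0.1 in every pair of libraries with the same replicate number. Neither table met it. The median was -0.00495 in the knockout table. In the double-loss table it was 0.305 with a lowest of 0.0909, and 26 of 30 such pairs lay above 0.1. A replicate effect in that table is therefore not excluded, and the main fit has no term for it. With 2 libraries per group the correlation with the other number is the negative of this one by construction, so it adds nothing.

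Within class B of the libraries the called genes were 544 for ARID2, 397 for BCL11A, 336 for BCL11B, 99 for DPF1, 237 for DPF2, 74 for DPF3, 317 for PBRM1, 262 for PHF10, 170 for SMARCA2, 423 for SMARCD1, 300 for SMARCD2, 132 between ARID1A clones and 172 between SMARCA4 clones; within class A they were 377 for BRD7, 295 for SMARCD2, and 108 and 196 between those clones. A fit of only the groups compared gave 155 for DPF1, 114 for DPF3, 286 for PHF10, 235 for SMARCA2, 134 between ARID1A clones, 114 for ARID2 knockout and 579 for SMARCA4 knockout in the double-loss table, 0 for wild type with both knockdowns, 141 for SMARCA4 knockdown in ARID2 knockout, 71 for its non-additivity and 0 genes in all double-loss groups. Against the other clones DPF3 had 381 and SMARCA2 536. With the replicate block ARID2 knockout had 397, wild type with both knockdowns 402 (132 up, 270 down), SMARCA4 knockdown in ARID2 knockout 800, ARID2 knockdown in SMARCA4 knockout 19, their non-additivity 386 and 80, and all double-loss groups 281; the block moved no other count by over 1.5 times. DESeq2 gave 231 for wild type with both knockdowns, 13 for ARID2 knockdown in SMARCA4 knockout, 339 and 96 for non-additivity and 147 for all double-loss groups; with 1 subtracted from each count these were 49 (31 up, 18 down), 1 and, for all groups, 33. The repeat between tables was 0.86 for ARID2 and 0.914 for SMARCA4 over called genes and 0.302 and 0.632 by Spearman, and 0.753 and 0.835 against the single SMARCA4 clones. With an estimated correlation 100 lists in the knockout table and 0 in the double-loss table were called.

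When each library was left out in turn, the counts ran from 0 to 86 for wild type with both knockdowns, 0 to 64 for all double-loss groups, 82 to 237 for ARID2 knockout, 691 to 1660 for ARID2 knockout with SMARCA4 knockdown, 710 to 1331 for SMARCA4 knockout with ARID2 knockdown, 63 to 864 and 0 to 3 for the knockdowns inside the knockouts, and 65 to 316, 17 to 40 and 327 to 542 for non-additivity.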

Other observations

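The test of partial loss and that of mixed states were planned before their values were known; those of library classes and chromosomes were chosen only after the result was seen, except depth and proliferation, and are given as values.

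Some members of the lists, picked after their values were seen, were called higher in some clones and lower in others. TAL1, a master regulator of blood formation, was called higher in 9 clones and lower in 14, with fold changes from -4.77 (SMARCC1 loss) to 2.06 (SMARCA2 loss), and it moved in opposite directions in the SMARCA4 clones (-2.39 and 1.76). NLRC5, the transactivator of class I genes, was called higher in 4 and lower in 3 (-2.12 to 3.45), PSMB8 in 3 and 12 (up to 4.73), the antiviral enzyme gene OAS2 in 3 and 15 (-3.97 to 2.32) and the matrix gene POSTN in 8 and 12 (-3.84 to 7.18). Whether these changes differ between knockouts was not tested.

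Wild type with both knockdowns had 82 called genes against 889 in the SMARCA4 knockout of the same table. A partial loss of SMARCA4 is a candidate explanation. Over the 889 genes the slope of its fold changes on those of the knockout was 0.212, with 0.255 for the library at 43.3 CPM of SMARCA4 and 0.168 for the one at 132 CPM, and a mean correlation of 0.518 across genes. A knockdown also acts for a shorter time than a knockout, which the design cannot separate.

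Some genes were called higher in at least 3 and lower in at least 3 clones. One hypothesis, formed on looking at the recurrent genes, was that such genes may mark states fixed when single cells were cloned from a mixed culture, whatever subunit was lost. Among 310 such genes picked without ARID1A and SMARCA4, the share called in the same direction in both clones of a gene was 95.7% for ARID1A (164 genes) and for SMARCA4 (209 genes). Pairs of clones of different genes had a median of 52.7% (75th percentile 62.8%, 95th 77.5%), so the test came out against the hypothesis in the form that was tested. Clones of 1 gene that descend from 1 edited cell could give the same share; 2 of 274 other pairs reached it, BCL11B with SMARCD3 (97.4%) and BCL11A with BCL11B (96.4%), and BCL11A with SMARCD3 had 95.3%. Among pairs of different genes these 3 clones also had the highest correlations of fold changes (0.71 to 0.802), so for them a shared state stays open.

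Residuals divided the knockout libraries, without SMARCC2, into 37 and 35 across the first component, which held 20.7% of the residual variance (7.88% for the second), and 24 groups had libraries of both classes. Between the classes 242 of 16098 genes were called. The reference annotation names 68.2% of the called and 89.9% of the tested genes. Among the genes it names, 47.3% of the called and 5.83% of the tested were pseudogenes by name. The probability that a library of the second class had the larger total was 0.677, and the median class effect was 0.00459 for mitotic and -0.0182 for E2F genes. Over 23 chromosomes and all clones the largest median fold change was 0.224 (SMARCC2, chromosome 19), and none reached 0.3.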
